A study of Mus musculus with 16 samples.

How the data were processed

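RNA was measured in 16 libraries, from the cerebral cortex and the cerebellum of 4 wild-type and 4 Mecp2 conditional knockout mice. Per the labels, libraries were made from poly-A selected RNA with the TruSeq kit, version 2. Per the submitters' processing notes, the authors trimmed reads with Trimmomatic 0.32, aligned them with STAR and counted them with featureCounts on the mouse build mm10 (GRCm38). The annotation release, the counting settings and the gene lengths used are not given in the sources used here. The authors deposited 1 table of RPKM (reads scaled by the length of the gene model in kilobases and by library size) for 52550 genes, with 1 column per library, and the values show no rescaling between libraries.

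The replicates are separate mice by their labels. Within groups, the correlation of log2 values between libraries was 0.944 to 0.982, and the chi-square of read differences per degree of freedom was 12.6 to 85.4, above what sequencing the same library again would give. Libraries of the same number in cortex and cerebellum are from the same mouse by the labels; wild-type mouse n and knockout mouse n are different animals. Correlations of the libraries' deviations from their group means were checked for pairing. Same-numbered cortex and cerebellum libraries gave 0.136 to 0.269 among knockout mice, against -0.241 to 0.0511 for other pairs, and -0.0749 to 0.170 among wild-type mice, against -0.168 to 0.157. Same-numbered wild-type and knockout libraries gave -0.490 to 0.0368 in the cerebellum and -0.271 to 0.0859 in the cortex, so they were not treated as pairs.

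Read counts were recovered from the smallest steps between RPKM values. Of the values of up to 100 reads, 95.4% to 95.9% per library lay within 0.05 of a whole number of reads. The read total of a library's RPKM was 28537932 to 31825685. Gene names, coordinates and spans came from the GENCODE mouse release M21 annotation, matched by gene ID; 52403 IDs matched and 147 did not, which held at most 0.042% of a library's RPKM.

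Tests were made with limma 3.58.1 in R 4.3.3 on log2(RPKM + 0.1), with the prior variance following mean expression and no further scaling. Genes with a mean of at least 0.5 RPKM over the libraries of a comparison were tested, two-sided, and called at a Benjamini-Hochberg adjusted p under 0.05. The pseudocount of 0.1 shrinks the fold changes of genes with low values. Knockout was compared with wild type within each tissue, from the 8 libraries of that tissue. The difference of the knockout effect between tissues, and wild-type cerebellum against wild-type cortex (called at 2-fold or more), came from a model of all 16 libraries with 4 groups, which treated the 2 libraries of a mouse as independent. With the mouse as a block (correlation 0.139), the smallest adjusted p of the difference of effects was 0.370, and 2833 genes passed between the wild-type tissues. Mecp2 was also tested with a two-sided exact permutation test of the difference of mean RPKM, which has 70 labelings.

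Gene groups were 41 lists of 1074 names, of which 3 names matched no gene; 39 lists had at least 5 measured members in each comparison. They were tested two-sided against the other genes with limma's camera, with a preset correlation between genes of 0.01 and then with the correlation estimated from each list, and with fry, which tests whether a list's genes move, on balance, in 1 direction. Adjustment was over the lists of a comparison. Some lists share members. Genes spanning at least 100 kb formed a further set. Median sizes of the lists kept their sign under median-ratio scaling and quantile normalization in all 58 comparisons made for the lists that passed.

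Named genes were chosen by a rule. Per knockout comparison it took the genes that passed, filled up with those of smallest p to 10 with a mean of at least 1 RPKM, which are said not to pass; for the interaction, the 10 genes of smallest p; for the tissues, the 8 genes most higher and the 8 most lower with a mean of at least 10 RPKM; and for each list described, up to 4 members of smallest p. A gene that this rule named was left out of the check for single libraries far from the rest of their group and is not reported here. Rps13, Rps13-ps2, Rps15a-ps8, Gdpd3 and Nmb were chosen after their values were seen. The tests, thresholds, gene lists, naming rule and most alternatives were fixed before the data were examined. The alternatives added later were voom on recovered reads, removal of a smooth trend with exon length and GC content, median-ratio scaling for lists, the mean of both tissues, and leaving out the 2 libraries per tissue that marker genes of other regions set apart.

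The procedure was tested on simulated data with the spread of these groups and 100 genes changed at each size. For 2-fold changes it recovered 81 in the cortex, 70 in the cerebellum and 58 for the interaction, and for 4-fold changes 87, 95 and 89. False calls were 14 of 182, 7 of 172 and 15 of 162. Genes of both sizes were changed in the same run, and many changed genes ease the Benjamini-Hochberg cutoff. Where few genes change, a smaller share of such changes would be recovered, so these shares do not give the power of the real comparisons. A set of 20 genes shifted by 0.5 on the log2 scale was called in both tissues, and 0 of 20 unshifted sets were. The simulated genes varied independently of each other, unlike the members of the real lists. The simulation thus cannot show how often correlated lists are called falsely. Alternatives covered the pseudocount, the expression filter, scaling, limma's variance settings, library weights, blocking, the list tests, length limits and leaving out each library. Tables were prepared with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.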

Results

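Messenger RNA was sequenced from the cerebral cortex and the cerebellum of 4 wild-type mice and 4 mice in which Mecp2 was deleted in adulthood, giving 16 libraries with 1 library per tissue and mouse. The knockout mice carried a floxed Mecp2 gene and a tamoxifen-activated Cre recombinase under a ubiquitously active promoter. The sample records of both genotypes list tamoxifen at 12 weeks of age for 5 days, behaviour at 16 weeks and tissue taken at 22 weeks. Expression was deposited as RPKM, reads scaled by gene model length and library size, for 52550 genes. The read total behind each library's values was between 28537932 and 31825685, so 1 read was a small fraction of an RPKM for most genes. Every library had the Y-linked transcripts Ddx3y, Uty, Eif2s3y and Kdm5d, and Xist was at most 0.0105 RPKM. Coordinates are on mouse genome build GRCm38, and values with ± are means and SD of 4 mice.

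The first question was how far the deletion had lowered Mecp2, which encodes a methyl-CpG binding protein. In the cortex, Mecp2 (ENSMUSG00000031393, chromosome X, 74026592 to 74135363, minus strand) fell from 8.54 ± 0.0429 RPKM in wild-type mice to 1.75 ± 1.58 RPKM in knockout mice, 20.5% of the wild-type mean (n = 4 and 4). In the cerebellum it fell from 9.17 ± 1.42 to 2.51 ± 1.93 RPKM, 27.4% of the wild-type mean. The exact permutation test gave a two-sided p = 0.0286 in each tissue, the smallest that 4 against 4 allows. The residual transcript was uneven between the knockout mice. In the cortex the 4 knockout mice, by number, kept 36.7%, 4.47%, 4.43% and 36.4% of the wild-type mean. Their cerebellum kept 41.1%, 12.0%, 6.90% and 49.4%. With this spread, limma's moderated test, adjusted over all genes, did not pass for Mecp2 itself, with a log2 fold change of -2.80 (SE 0.66) and adjusted p = 0.702 in the cortex and of -2.21 (SE 0.54) and adjusted p = 0.303 in the cerebellum. Limma's test of the difference between the tissues gave an unadjusted p = 0.532 for Mecp2. Leaving out 1 mouse raises the smallest possible exact p to 0.0571.

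Irak1, an interleukin-1 receptor associated kinase encoded next to Mecp2 (chromosome X, 74013914 to 74023918, minus strand), had 10.01 ± 0.312 RPKM in wild-type and 16.4 ± 4.39 RPKM in knockout cortex, and 12.7 ± 0.382 and 20.7 ± 7.02 RPKM in the cerebellum. Its log2 fold changes of 0.67 (SE 0.17) and 0.63 (SE 0.21) did not pass over all genes (adjusted p = 0.759 and 0.303). In each tissue, nevertheless, the 4 knockout libraries lay above the 4 wild-type libraries. Per knockout mouse, by number, Irak1 was 132%, 204%, 199% and 120% of the wild-type mean in the cortex and 117%, 201%, 219% and 113% in the cerebellum. As a group, the 25 measured X-linked neighbours of Mecp2 did not pass in either tissue, with medians of 0.0234 in the cortex (camera adjusted p = 0.777) and -0.10 in the cerebellum (adjusted p = 0.178).

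**Figure D1:**
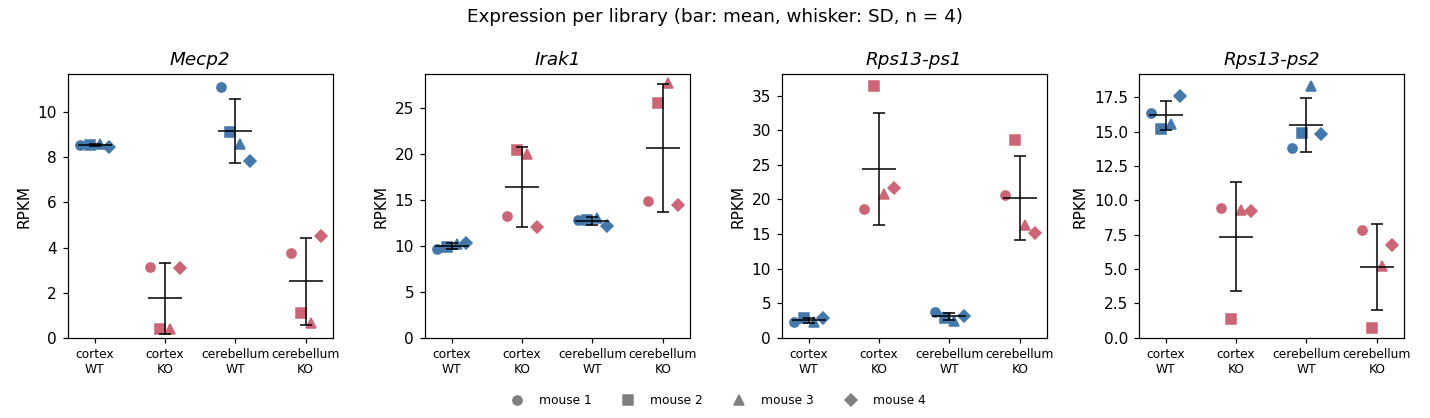
RPKM of Mecp2, Irak1, Rps13-ps1 and Rps13-ps2 in each of the 16 libraries by tissue and genotype (blue, wild type; red, knockout; horizontal bar, mean; whisker, SD of 4 mice; symbols, mouse number within its genotype). Mecp2 is lower in every knockout library, at 0.378 to 4.53 RPKM, and Rps13-ps1 is higher in every one, at 15.2 to 36.4 RPKM.

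The second question was which genes differed between knockout and wild-type cortex. A single transcript passed, and it was higher in knockout mice. It was Rps13-ps1, a processed pseudogene of the ribosomal protein gene Rps13 (ENSMUSG00000066362, chromosome 8, 87047689 to 87048226). It went from 2.54 ± 0.360 to 24.4 ± 8.12 RPKM, a log2 fold change of 3.17 (SE 0.20) with adjusted p = 0.00151 (limma, n = 4 and 4), and was above every wild-type value in 4 of 4 knockout mice. Reads can be shared between near-identical copies of Rps13, so the transcript they came from is uncertain. Another copy, Rps13-ps2 (chromosome 7, 88530446 to 88530898), had 16.2 ± 1.07 RPKM in wild-type and 7.34 ± 3.96 RPKM in knockout cortex (adjusted p = 0.884), and Rps13 itself 21.4 ± 0.952 and 20.8 ± 1.68 RPKM (adjusted p = 0.974). Without knockout mouse 2, Rps13-ps2 also passed in the cortex.

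No other cortical gene passed. Those of smallest p included the stress neuropeptide gene Crh, at 3.92 ± 0.660 RPKM in wild-type and 2.04 ± 0.232 RPKM in knockout cortex (log2 fold change -0.90, SE 0.13, limma adjusted p = 0.450). The T-type calcium channel gene Cacna1g had a fold change of -0.65 (SE 0.0966), the BMP antagonist gene Nog -0.58 (SE 0.0928) and the cathepsin gene Ctsk -0.64 (SE 0.11). On the other side, the mesoderm segmentation gene Ripply2 had 0.67 (SE 0.10), Sh3bgrl2 0.46 (SE 0.0827), Cd99l2 0.31 (SE 0.0548), and the predicted genes Gm39822 and Gm2606 -0.93 and 0.36. Of 15032 genes tested in the cortex with limma, 1 was higher, 0 were lower, and 808 had an unadjusted p under 0.05 (439 higher, 369 lower), against 752 by chance. The share that was higher, 54.3%, was 52.1% with median-ratio scaling and 45.4% with quantile normalization (372 higher, 447 lower). The 808 became 1212 without knockout mouse 1.

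Among gene groups in the cortex, protein-folding genes shifted down and vascular and meningeal genes shifted up against the other genes, by camera with its preset correlation. The heat shock and unfolded protein response list had a median log2 fold change of -0.19, with 23 of 26 members negative and 8 of them lower at an unadjusted p under 0.05 (camera adjusted p = 3.54e-09, and adjusted p = 0.554 with an estimated correlation). Adjusted over the list alone, 5 members were lower, and 0 were over all genes. Its members of smallest p were the stress transcription factor gene Ddit3 (-0.29, SE 0.0609), the endoplasmic reticulum co-chaperone gene Dnajb11 (-0.26, SE 0.0636), the secreted factor gene Manf (-0.32, SE 0.0853) and the disulfide isomerase gene Pdia6 (-0.35, SE 0.0936). Meninges and fibroblast markers had a median of 0.48, with 16 of 17 members positive and 6 higher at an unadjusted p under 0.05 (adjusted p = 5.58e-08, and adjusted p = 0.554 with an estimated correlation). Among them were the extracellular matrix genes Fmod (0.91, SE 0.26), Bgn (0.43, SE 0.13) and Ogn (0.85, SE 0.27) and the organic anion transporter gene Slc22a6 (0.81, SE 0.26). All 18 endothelial markers were positive, with a median of 0.26 (adjusted p = 2.31e-07, and adjusted p = 0.554 with an estimated correlation). They included the receptor genes Tek (0.41, SE 0.12) and Tie1 (0.42, SE 0.15) and the junction genes Cdh5 (0.30, SE 0.11) and Pecam1 (0.30, SE 0.11). Mural cell markers had a median of 0.28, with 9 of 11 positive (adjusted p = 6.34e-04, and adjusted p = 0.513 with an estimated correlation). In each of these vascular and meningeal lists, 0 members passed when adjusted over the list alone or over all genes. For meninges markers, wild-type mice scored -0.36 to 0.47 and knockout mice 0.10 to 0.78. For heat shock genes, wild-type mice scored -0.19 to 0.19, and knockout mouse 2 scored 0.0496. Endothelial scores overlapped too (wild-type mouse 2 at 0.13, knockout mouse 4 at 0.12), and mural cell scores did not.

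Other cortical groups passed by camera's preset correlation and not with an estimated one. Reactive glia, complement and MHC class I genes had a median of 0.18 over 20 genes (camera adjusted p = 0.0159, and adjusted p = 0.655 with an estimated correlation), with H2-D1 at 0.41 (SE 0.14) and Serping1 at 0.71 (SE 0.29). Synaptic vesicle and scaffold genes had a median of -0.0451 over 35 genes (adjusted p = 0.00676, and adjusted p = 0.513 with an estimated correlation), with the active zone gene Rims1 at -0.23 (SE 0.0678) and the postsynaptic scaffold gene Shank2 at -0.24 (SE 0.0859). Axon guidance and cell adhesion genes had a median of 0.0820 over 65 genes (adjusted p = 0.0218, and adjusted p = 0.655 with an estimated correlation), with the ephrin receptor genes Epha3 at 0.51 (SE 0.17) and Epha7 at 0.40 (SE 0.14). The 5 blood cell markers had a median of 0.51 (adjusted p = 0.0363, and adjusted p = 0.658 with an estimated correlation). The 25 imprinted genes had a median of 0.0958 (adjusted p = 0.0363, and adjusted p = 0.655 with an estimated correlation), with Nap1l5 at 0.47 (SE 0.12). Once a smooth trend with exon length and GC content was removed from each library, the imprinted genes did not pass (median 0.0645, adjusted p = 0.0761). These calls depended on single libraries. Blood cell markers lost theirs without wild-type mouse 3 or 4 or knockout mouse 1 or 4 (0.44, 0.46, 0.45 and 0.21), reactive glia genes without wild-type mouse 3 or 4 or knockout mouse 2 or 4 (0.11, 0.15, 0.16 and 0.0779), imprinted genes without wild-type mouse 1, 3 or 4 or knockout mouse 2 (0.0879, 0.0659, 0.0310 and 0.0434), axon guidance genes without wild-type mouse 4 or knockout mouse 4 (0.0411 and 0.0544) and synaptic genes without knockout mouse 1 (-0.0559). Adjusted over the list alone or over all genes, 0 members of these groups passed. The 34 genes reported in the literature as MeCP2 targets had a median of -0.0232, with 3 higher and 1 lower at an unadjusted p under 0.05; adjusted over the list alone 1 was lower, and as a group they did not pass (adjusted p = 0.777).

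**Figure D2:**
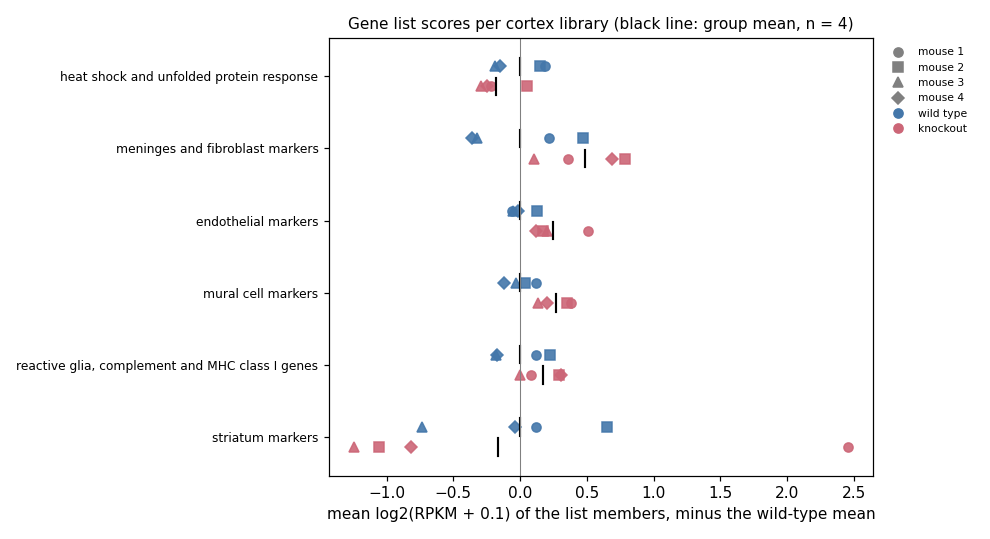
Scores of 6 gene lists in the 8 cortex libraries (x axis, mean log2(RPKM + 0.1) of the list's members minus the wild-type mean; blue, wild type; red, knockout; black line, group mean of 4 mice; symbols, mouse number within its genotype). Knockout mouse 1 stands apart from the rest in striatum markers, with a score of 2.46.

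In all, 9 of 39 lists passed in the cortex by camera's preset correlation, 7 up and 2 down, and 0 passed by fry, the directional rotation test, whose smallest adjusted p was 0.361. Fry's test of change in either direction passed for 1 list, interferon response genes (adjusted p = 1.00e-05), of which 12 were positive and 6 negative. At an unadjusted p under 0.05, 2 of them were higher and 1 lower, and adjusted over the list alone 1 was lower. In 1 direction this list did not pass (camera adjusted p = 0.243). The 30 lists that camera's preset correlation did not call had adjusted p from 0.0717 to 0.949. A list's median and mean differed in sign in 6 of the 39, as did its median and camera's direction in 6. Some cortex libraries stood apart by markers of neighbouring regions. Knockout mouse 1 had 295 RPKM of the striatal neuropeptide gene Penk, 35.7 RPKM of the adenosine receptor gene Adora2a and 10.2 RPKM of the hypothalamic gene Hcrt, against at most 20.8, 1.501 and 0.0889 RPKM in the other knockout mice. Wild-type mouse 2 had 957 RPKM of the choroid plexus gene Ttr, against at most 39.2 RPKM in the other wild-type mice. Without knockout mouse 1, 15 lists passed rather than 9.

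The third question was which genes differed between knockout and wild-type cerebellum. Rps13-ps1 rose there too, from 3.09 ± 0.539 to 20.2 ± 6.08 RPKM (log2 fold change 2.64, SE 0.20, limma adjusted p = 0.00774, n = 4 and 4), and was above every wild-type value in 4 of 4 knockout mice, again with reads that near-identical copies can share. Rps13-ps2 had 15.4 ± 1.97 RPKM in wild-type and 5.14 ± 3.14 RPKM in knockout cerebellum (adjusted p = 0.303). Of 15702 genes tested with limma, 1 was higher, 0 were lower, and 2544 had an unadjusted p under 0.05 (842 higher, 1702 lower), against 785 by chance. The share of those 2544 that was higher, 33.1%, was 41.8% with median-ratio scaling and 49.5% with quantile normalization, so the excess of lower genes depended on scaling.

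After it in the cerebellum came Rps15a-ps8, a ribosomal protein pseudogene under a mean of 1 RPKM, which did not pass (limma adjusted p = 0.0594). The next genes of smallest p had adjusted p = 0.303 and did not pass. They were the neuronal adhesion genes Cntn4 (0.55, SE 0.0875) and Kirrel3 (0.49, SE 0.0953), the predicted gene Gm42528 (0.76, SE 0.13), the retinoic acid binding gene Crabp1 (-2.38, SE 0.44), the tRNA guanylyltransferase gene Thg1l (-0.65, SE 0.12) and the dynein light chain gene Dynll1 (-0.51, SE 0.10). The predicted genes Gm5575, Gm5566 and Gm32256 had -0.71, -0.82 and -0.87.

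Gene groups parted by cell type in the cerebellum. Granule cell markers had a median log2 fold change of 0.52, with 18 of 19 positive and 15 higher at an unadjusted p under 0.05 (camera adjusted p = 1.55e-11, and adjusted p = 0.568 with an estimated correlation). Adjusted over the list alone, 14 were higher, and 0 were over all genes. Examples were the vesicle release gene Rims3 (0.47, SE 0.13) and the transcription factor genes Etv1 (0.62, SE 0.18), Neurod1 (0.65, SE 0.21) and Zic2 (0.57, SE 0.18). Purkinje cell markers had a median of 0.32, with 20 of 21 positive (adjusted p = 4.35e-06, and adjusted p = 0.568 with an estimated correlation), among them Lhx1 (0.51, SE 0.16), Lhx5 (0.41, SE 0.14) and Homer3 (0.46, SE 0.21); the list also holds Gdf10 (0.59, SE 0.19), which is known from Bergmann glia too. All 26 oligodendrocyte and myelin genes were negative, with a median of -0.45 (adjusted p = 1.29e-05, and adjusted p = 0.594 with an estimated correlation), including the myelin genes Mbp (-0.73, SE 0.30), Mobp (-0.87, SE 0.32) and Mag (-0.58, SE 0.24). All 19 microglia markers were negative, with a median of -0.43 (adjusted p = 4.99e-05, and adjusted p = 0.568 with an estimated correlation), including the complement genes C1qa (-0.48, SE 0.18) and C1qc (-0.53, SE 0.15). In the Purkinje, myelin and microglia lists, 0 members passed when adjusted over the list alone or over all genes. The myelin score was 0.0212 in knockout mouse 1 and -1.09, -0.50 and -0.33 in mice 2, 3 and 4.

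Transmitter and peptide genes shifted down in the cerebellum as well. Less non-cerebellar or deep tissue in some dissections is a candidate explanation, taken up further below, and was not told apart from an effect of genotype. Neuropeptide genes had a median of -1.33, with 18 of 24 lower at an unadjusted p under 0.05 (camera adjusted p = 3.46e-05, and adjusted p = 0.568 with an estimated correlation). Adjusted over the list alone 14 were lower, and 0 were over all genes; with the trend in exon length and GC content removed, 0 were lower over the list alone in limma, and 14 had an unadjusted p under 0.05. The members of smallest p were Nxph4 (-1.50, SE 0.39), Adcyap1 (-1.63, SE 0.52), Vgf (-1.85, SE 0.59) and the thyrotropin-releasing hormone gene Trh (-3.26, SE 1.09). Monoamine synthesis and transport genes had a median of -0.70, with 12 of 13 negative (adjusted p = 4.99e-05, and adjusted p = 0.568 with an estimated correlation). Adjusted over the list alone 7 were lower, and 0 were over all genes; examples were the vesicular monoamine transporter gene Slc18a2 (-1.75, SE 0.40), the noradrenaline-synthesizing Dbh (-3.34, SE 0.96) and the noradrenaline transporter gene Slc6a2 (-2.59, SE 0.81). Thalamus, hypothalamus and brainstem markers had a median of -1.37 over 16 genes and did not pass (adjusted p = 0.0537). With the trend in exon length and GC content removed they passed, with a median of -1.27 (adjusted p = 0.00475, and adjusted p = 0.599 with an estimated correlation). The neuropeptide score was -0.22 in knockout mouse 1 and -2.61, -1.60 and -0.71 in mice 2, 3 and 4.

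Genes of protein synthesis and respiration also shifted down as groups in the cerebellum. Of 79 cytosolic ribosomal protein genes, 78 were negative, with a median of -0.31 and 54 lower at an unadjusted p under 0.05 (camera adjusted p = 3.72e-17, and adjusted p = 0.568 with an estimated correlation), for example Rps16 (-0.32, SE 0.0912) and Rps28 (-0.33, SE 0.0890). All 75 nuclear genes of oxidative phosphorylation were negative, with a median of -0.23 (adjusted p = 8.04e-12, and adjusted p = 0.568 with an estimated correlation), for example Uqcrb (-0.30, SE 0.0808) and Cox7c (-0.31, SE 0.0917). All 13 mitochondrially encoded genes were negative too, with a median of -0.30 (adjusted p = 0.00129, and adjusted p = 0.619 with an estimated correlation). Heat shock and unfolded protein response genes had a median of -0.26, with 26 of 26 negative (adjusted p = 7.94e-06, and adjusted p = 0.568 with an estimated correlation), including the small chaperone gene Hspb1 (-0.51, SE 0.13). Cholesterol biosynthesis and uptake genes had a median of -0.30, with 23 of 24 negative (adjusted p = 3.46e-05, and adjusted p = 0.568 with an estimated correlation), including Nsdhl (-0.76, SE 0.24) and Hmgcs1 (-0.57, SE 0.21). With the trend in exon length and GC content removed, the medians were nearer to 0: -0.14 for ribosomal genes (17 lower at an unadjusted p under 0.05), -0.0547 for nuclear respiration genes (5 lower), -0.13 for mitochondrial, -0.14 for heat shock and -0.19 for cholesterol genes. All 5 then passed by camera (largest adjusted p = 0.00503, and adjusted p = 0.599 or above with an estimated correlation), while with quantile normalization the mitochondrial genes did not (-0.18, adjusted p = 0.0501). In all 5 groups, 0 members passed when adjusted over the list alone or over all genes. The ribosomal score was 0.0237 in knockout mouse 1 and -0.42, -0.38 and -0.46 in mice 2, 3 and 4.

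The remaining 9 cerebellar groups that passed by camera shifted up, and 5 of them did not pass with the trend removed: axon guidance (adjusted p = 0.523), channel (0.524), synaptic (0.153), endothelial (0.0911) and glucocorticoid response genes (0.0678). Circadian clock genes had a median of 0.22 (adjusted p = 4.99e-05, and adjusted p = 0.568 with an estimated correlation), with Bhlhe40 at 0.35 (SE 0.0937) and Cry1 at 0.48 (SE 0.17). MeCP2 partners and DNA methylation genes had a median of 0.16 (adjusted p = 9.28e-04, and adjusted p = 0.568 with an estimated correlation), with the DNA methyltransferase gene Dnmt3a at 0.28 (SE 0.11) and the kinase gene Cdkl5 at 0.40 (SE 0.16). Axon guidance and cell adhesion genes had a median of 0.11 (adjusted p = 9.28e-04, and adjusted p = 0.620 with an estimated correlation); adjusted over the list alone, 1 of 62 was higher, against 0 over all genes and 0 in the other groups of this paragraph. Potassium, sodium and calcium channel genes had a median of 0.14 but a mean of -0.0157 (adjusted p = 9.34e-04, and adjusted p = 0.568 with an estimated correlation), with Kcnc1 at 0.43 (SE 0.11) and Scn3b at -2.16 (SE 0.67). Synaptic vesicle and scaffold genes had a median of 0.0830 (adjusted p = 0.00417, and adjusted p = 0.568 with an estimated correlation), and the 6 blood cell markers 0.72 (adjusted p = 0.00736, and adjusted p = 0.568 with an estimated correlation). Endothelial markers had 0.20 (adjusted p = 0.0332, and adjusted p = 0.620 with an estimated correlation), glucocorticoid response genes 0.0911 (adjusted p = 0.0376, and adjusted p = 0.620 with an estimated correlation) and immediate early genes 0.14 (adjusted p = 0.0426, and adjusted p = 0.568 with an estimated correlation). Leaving out 1 library ended the call of blood cell markers without knockout mouse 4 (0.39), axon guidance genes without wild-type mouse 3 or knockout mouse 4 (0.0192 and 0.0454), endothelial markers without wild-type mouse 2 or 3 or knockout mouse 3 or 4 (0.13, 0.11, 0.12 and 0.10), glucocorticoid response genes without wild-type mouse 1, 2 or 3 or knockout mouse 2 (-0.00225, 0.0960, -0.0350 and -0.0656) and immediate early genes without wild-type mouse 2 or 4 or knockout mouse 1, 3 or 4 (0.0914, -0.00935, 0.12, 0.0924 and 0.13). The endothelial, glucocorticoid response and immediate early lists also lost their calls with median-ratio scaling (adjusted p = 0.0534, 0.0667 and 0.0667) and quantile normalization (0.0983, 0.0981 and 0.101). The 31 measured genes reported in the literature as MeCP2 targets had a median of -0.0847 and a mean of -0.33, while camera's direction was up, and did not pass (adjusted p = 0.910).

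**Figure D3:**
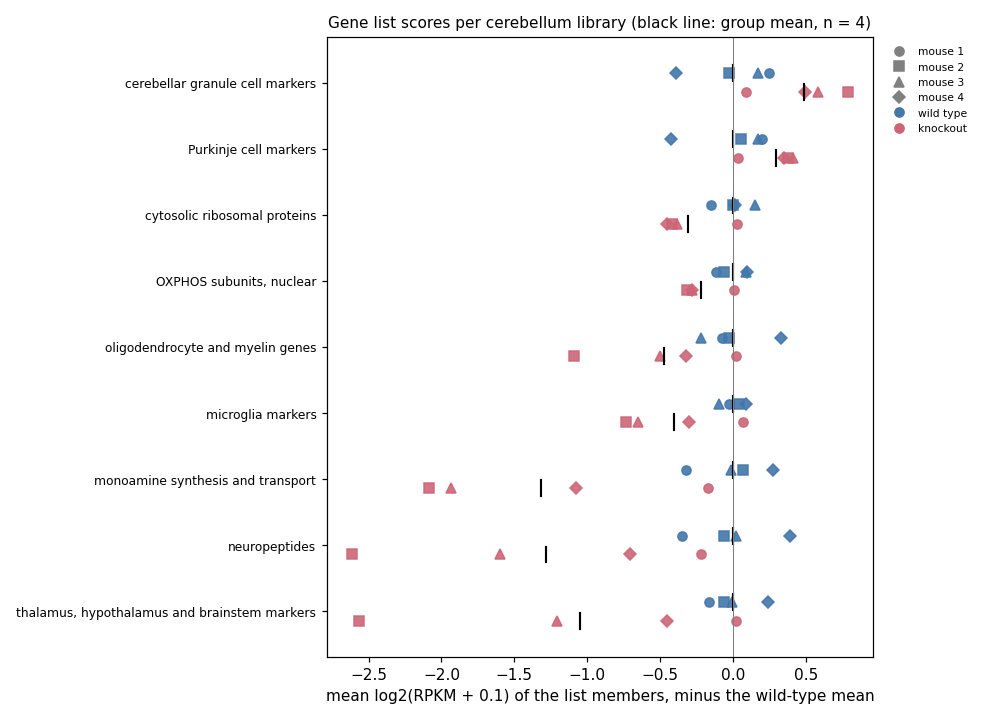
Scores of 9 gene lists in the 8 cerebellum libraries (x axis, mean log2(RPKM + 0.1) of the list's members minus the wild-type mean; blue, wild type; red, knockout; black line, group mean of 4 mice; symbols, mouse number within its genotype). Knockout mouse 1 lies near the wild-type mice, with a brainstem marker score of 0.0211, while knockout mouse 2 lies farthest from them, at -2.56.

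In all, 20 of 39 lists passed in the cerebellum by camera's preset correlation, 11 up and 9 down; with median-ratio scaling 8 were up and 11 down, and with quantile normalization 8 up and 10 down. With the exon length and GC trend removed, choroid plexus markers (-0.74, with scores before removal of -3.27 in knockout mouse 3 and -0.14 to 0.19 in the other knockout mice), imprinted genes (-0.30) and oligodendrocyte precursor markers (-0.27) also passed (adjusted p = 0.00367, 0.00367 and 0.0151, and adjusted p = 0.765, 0.599 and 0.599 with an estimated correlation). By fry, 0 passed in 1 direction, with a smallest adjusted p of 0.319, or in either direction. The other 19 lists had adjusted p from 0.0537 to 0.958, and a list's median and mean differed in sign in 6 of the 39, and its median and camera's direction in 5. These shifts were uneven between the knockout mice. The granule cell score was 0.0892 in knockout mouse 1 against 0.79, 0.58 and 0.49 in mice 2, 3 and 4, and the brainstem marker score was 0.0211 against -2.56, -1.21 and -0.45. The first principal component of the cerebellum libraries, with 47.8% of the variance, placed knockout mouse 1 at -22.0, among the wild-type mice at -38.0 to -3.00, and the others at 16.9 to 58.1.

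The cerebellar call of Rps13-ps1 and the count of 1 gene depended on single libraries. With limma, 0 genes passed without wild-type mouse 2, 3 or 4 (1495, 1692 and 1085 at an unadjusted p under 0.05) or by voom on recovered reads (2620), 1254 passed without knockout mouse 1 (407 higher, 847 lower), and 4574 passed when libraries were weighted by their quality. The 2544 genes at an unadjusted p under 0.05 became 5040, 1172, 1158 and 1832 without knockout mouse 1, 2, 3 or 4, 3301 without wild-type mouse 1 and 6893 with library weights.

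The fourth question was whether the knockout effect differed between the tissues. By limma's interaction test 0 of 15587 genes passed, 1571 had an unadjusted p under 0.05 (451 with a more positive effect in the cerebellum and 1120 with a more negative one), and the smallest adjusted p was 0.494. The calcium channel gene Cacna1g was among the genes of smallest p, with a difference of 0.99 (SE 0.20) between a cortical fold change of -0.65 and a cerebellar one of 0.35. The others were Csdc2, which encodes an RNA-binding protein (0.43, SE 0.10), the small GTPase gene Rab42 (-1.01, SE 0.25), and pseudogenes and predicted genes such as Gm9083 (-1.12, SE 0.22), H3f3a-ps2 (0.44, SE 0.0954) and Gm9803 (-0.59, SE 0.14). Among groups, 17 of 39 lists passed by camera's preset correlation (7 with a more positive effect in the cerebellum, 10 with a more negative one) and 0 with an estimated correlation, where the smallest adjusted p was 0.443, or by fry. All 78 cytosolic ribosomal protein genes had a more negative effect in the cerebellum, by a median of -0.33 (adjusted p = 8.04e-19, and adjusted p = 0.540 with an estimated correlation). Neuropeptide genes differed by -1.27 (adjusted p = 9.17e-04, and adjusted p = 0.594 with an estimated correlation), and granule cell markers by 0.46 (adjusted p = 3.19e-07, and adjusted p = 0.443 with an estimated correlation). The heat shock list, shifted down in both tissues, did not pass the test of the difference (adjusted p = 0.549). The count of genes was 339 without the cerebellum of knockout mouse 1, 1 without the cortex of knockout mouse 2, and 1598 with library weights.

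The effects of the tissues were also set side by side. Across 14328 genes tested in both, which are not independent replicates, the fold changes had a Pearson correlation of 0.238, and 54.8% had the same sign. Rps13-ps1 was the 1 gene called in both tissues. At an unadjusted p under 0.05 in each tissue, 48 genes were higher in both and 97 lower in both, where 23.3 and 37.7 were given by chance for independent tissues; these tissues came from the same mice. Other splits of the mice into groups of 4 varied in this. A split that mixed the genotypes evenly gave 36 and 22 genes against 3.92 and 4.13. Another split gave 34 and 40 against 34.2 and 37.1. An excess over chance thus also arose without a difference in genotype.

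Gene length was compared because long genes are often discussed for MeCP2. In the cerebellum, the 2033 genes spanning at least 100 kb had a median log2 fold change of 0.0826 against -0.0652 for the 13646 shorter ones, a difference of 0.148 (camera p = 2.16e-10, p = 0.114 with an estimated correlation). In the cortex, 2032 long genes had a median of 0.0291 against 0.00319 for 12980 shorter ones, a difference of 0.0259 (camera p = 0.0353, p = 0.189 with an estimated correlation). Fry, which tests the long genes against no change rather than against the other genes, did not pass in either tissue. Across genes, the Spearman correlation of fold change with span was 0.281 in the cerebellum and 0.0279 in the cortex. Once a smooth trend with exon length and GC content was removed from each library, the differences were 0.0306 in the cerebellum and 0.0192 in the cortex, and neither passed by camera. The cortical call also ended without wild-type mouse 2 or 4 or knockout mouse 1 or 4 (differences of 0.0235, 0.0225, 0.0129 and 0.0219).

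The last comparison, cerebellum against cortex in wild-type mice, checked tissue identity. Granule and Purkinje cell genes were far higher in the cerebellum. The GABA receptor subunit gene Gabra6 was higher by 10.24 (SE 0.20) on the log2 scale, with 149 ± 24.7 RPKM against 0.0230 ± 0.0219 RPKM in the cortex, a size that depends on the pseudocount at so low a level, the synaptic organizer gene Cbln3 by 9.62 (SE 0.24), the Purkinje cell genes Ppp1r17 by 8.45 (SE 0.31) and Pcp2 by 8.41 (SE 0.21), and the glycine transporter gene Slc6a5 by 7.63 (SE 0.34). Cnpy1, Fat2 and Lhx1os followed at 8.09, 7.88 and 7.50. Lower in the cerebellum were the dendritic gene Ddn (-8.57, SE 0.55), the thyroid hormone binding gene Crym (-7.04, SE 0.40), the potassium channel genes Kcnj4 (-6.96, SE 0.27), Kcnv1 (-6.08, SE 0.32) and Kcnh3 (-6.03, SE 0.21), the activity-regulated transcription factor gene Egr3 (-6.32, SE 0.38), the muscarinic receptor gene Chrm1 (-6.26, SE 0.24) and Gm11549 (-7.09, SE 0.26). The adjusted p of these 16 genes was at most 6.12e-09 (limma). At 2-fold or more, 1699 genes were higher and 1110 lower in the cerebellum; with quantile normalization 1266 and 1387 were, and with median-ratio scaling 1455 and 1238.

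Members of lists were counted as called here at an adjusted p under 0.05, without the 2-fold limit used for the gene counts above. By group, 20 of 21 Purkinje cell markers and 16 of 19 granule cell markers were called higher in the wild-type cerebellum, with medians of 3.20 (camera adjusted p = 2.60e-11, and adjusted p = 0.209 with an estimated correlation) and 3.84 (adjusted p = 1.37e-07, and adjusted p = 0.333 with an estimated correlation). Cortical excitatory neuron markers were lower, 18 of 22 of them called, with a median of -2.41, and kept adjusted p = 0.0310 with an estimated correlation. Microglia markers (19 of 20 called lower) had a median of -0.98 (adjusted p = 7.81e-09, and adjusted p = 0.398 with an estimated correlation), and immediate early genes (17 of 26 called lower) -2.02 (adjusted p = 1.24e-07, and adjusted p = 0.373 with an estimated correlation). In all, 21 lists passed by camera's preset correlation (8 up, 13 down), 1 with an estimated correlation and 25 by fry.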

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

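The test of depth was chosen after the result was seen; the other tests in this part were chosen before it. Of 336 groups of 4 libraries checked, over 168 pairs of a named gene and a tissue, 23 had 1 library far from the other 3. Chance flags about 1 in 20 groups, or 5%.

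In the cortex of knockout mouse 1, genes of striatum and hypothalamus were far above the nearest other knockout library: Penk at 295 against 20.8 RPKM, Adora2a at 35.7 against 1.501, Tac1 at 26.1 against 2.90 and Hcrt at 10.2 against 0.0889. In the cortex of wild-type mouse 2, the choroid plexus genes Ttr (957 against 39.2 RPKM), Clic6 (4.60 against 0.652) and Sostdc1 (2.43 against 0.759) were high, and Foxp1 was low at 4.84 against 5.54. Ripply2 was highest in wild-type mouse 1 (2.60 against 2.23) and Fam3a in wild-type mouse 3 (7.29 against 6.47).

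In the cerebellum of knockout mouse 1, Gdf10 (48.8 against 63.2 RPKM), Rora (14.8 against 23.7) and Slit3 (2.14 against 2.93) were low, and Trh (3.54 against 0.403) was high among the knockout mice. In knockout mouse 3, the choroid plexus genes Calml4 (0.138 against 0.872) and Steap1 (0.137 against 1.41) were low. Among wild-type mice, number 4 was high in Vgf (37.8 against 23.5), Nsdhl (9.65 against 7.30) and Nfkbia (18.3 against 12.3). Wild-type mouse 1 was high in Trpm3 (18.1 against 10.4) and low in Pmvk (18.5 against 21.6) and Gm32256 (1.34 against 1.49), and wild-type mouse 3 was low in Ctss (21.5 against 26.7).

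Several of these values belong to lists that parted in the knockout cerebellum, where granule cell markers were higher and brainstem, peptide, monoamine and myelin genes lower. A trend with exon length and GC content is argued against, since the granule cell median was 0.57 after the trend was removed and 0.52 before, and so is depth, since mean read totals differed by 1.42%. A candidate explanation is that less non-cerebellar or deep tissue was dissected with some cerebella: over the 8 libraries, deviations from the group means of the granule cell score and of the mean brainstem, peptide and monoamine score had a Pearson correlation of -0.80 (exact permutation p = 0.00694, 1 relation tested) and a Spearman correlation of -0.79 (p = 0.0243, of 576 permutations within groups). Without knockout mice 2 and 1, the farthest from the median, the Pearson correlation was -0.60. Among the knockout mice, the granule cell deviation was 0.299 and 0.0942 in mice 2 and 3, which kept 12.0% and 6.90% of wild-type Mecp2. It was -0.398 and 0.00503 in mice 1 and 4, which kept 41.1% and 49.4%. Among the knockout mice, the correlation thus cannot tell dissection apart from an effect that follows the residual Mecp2. An effect of genotype stays open as well, as untested.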

How the results depend on the processing

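The fits with voom, with a length and GC trend removed, for the mean of both tissues, without 2 doubted libraries per tissue, and with median-ratio scaling of lists were chosen after the data were seen. Apart from the alternatives given below, each result kept its side of the threshold, and total counts of genes and lists called stayed within 1.5 times. The balance of higher and lower did turn with quantile normalization: 1266 genes were higher and 1387 lower in the wild-type cerebellum against 1699 and 1110, 372 and 447 at an unadjusted p under 0.05 in the knockout cortex against 439 and 369, and 8 lists up and 10 down in the knockout cerebellum against 11 and 9. The median fold change of all cerebellar genes went from -0.0502 to 0.0156. The cause was not tested for any change below except where fewer libraries or genes were used. For the lists that passed, 114 of 151 alternatives in the cortex and 269 of 340 in the cerebellum kept the call, and 37 and 71 lost it. The median of glucocorticoid response genes in the cerebellum turned negative without wild-type mouse 1 or 3 or knockout mouse 2 (-0.00225, -0.0350 and -0.0656), and that of immediate early genes without wild-type mouse 4 (-0.00935), each without a call.

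Rps13-ps1 was among the genes called in the cortex under every alternative. With no expression filter the count of genes was 3 in the cortex, 9 in the cerebellum and 7 for the interaction, with genes under 0.5 RPKM added to the test. Leaving out 1 library gave 1 to 2 genes in the cortex (with Gdpd3 added without wild-type mouse 1, Rps13-ps2 without knockout mouse 2 and Nmb without knockout mouse 4), 0 to 1254 in the cerebellum (0 without wild-type mouse 2, 3 or 4; 1254 without knockout mouse 1), 0 to 339 for the interaction and 2 to 37 for the mean of both tissues (37 without knockout mouse 1). In the cerebellum the count was 2 without a mean-variance trend, 2 with all 16 libraries in 1 model, 2 at an adjusted p under 0.1, 4574 with library weights, 0 by voom (2620 at an unadjusted p under 0.05) and 7 without 2 doubted libraries. Library weights gave 1598 for the interaction. With the replicate number as a block, which does not pair these mice, limma called 1 gene in the cortex and 0 in the cerebellum (1660 at an unadjusted p under 0.05). For wild-type tissues the count was 1687 with a pseudocount of 1 and 1701 at a mean RPKM of at least 2, against 2809, and 2620 to 2905 leaving out 1 library.

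Lists called fell to 0 with an estimated correlation and 0 by fry in both tissues. In the cortex they were 15 without 2 doubted libraries and 8 to 15 leaving out 1 library (15 without knockout mouse 1); in the cerebellum 17 to 23. The long-gene difference of 0.0259 in the cortex and 0.148 in the cerebellum did not pass with an estimated correlation. By fry, which tests the long genes against no change and not this difference, the long genes did not pass in either tissue. In the cortex it lost its call at 0.0194 with a mean RPKM of at least 2, 0.0127 with a 50 kb limit and 0.0192 with the trend removed, and was 0.0129 to 0.0328 leaving out 1 library; in the cerebellum it was 0.0306 with the trend removed and 0.107 to 0.205 leaving out 1 library. Mecp2 stayed at 15.1% to 25.9% of wild type in the cortex and 20.01% to 34.2% in the cerebellum, with an exact p of 0.0571 at the smallest. Depth limits what can be said of transcripts of few reads, such as Rps15a-ps8 with 0 to 17 reads per library.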

Other observations

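In this part, the mean of both tissues, the reads of Rps13 copies, the test of a sequence variant and the splits at an unadjusted p were chosen after the result was seen, and the rest before it. The mean effect over both tissues came from a limma model of all 16 libraries with tissue and genotype. The mouse was a block (correlation 0.0807), so the 2 libraries of a mouse counted as nearly independent. In this fit, 2 genes were higher in knockout mice. They were Rps13-ps1 (log2 fold change 2.90, SE 0.17, adjusted p = 1.60e-07) and Ripply2 (0.56, SE 0.0781, adjusted p = 0.0199; chromosome 9, 87015537 to 87019917), a gene of somite segmentation. Ripply2 was 2.30 ± 0.204 RPKM in wild-type and 3.71 ± 0.438 RPKM in knockout cortex and 3.87 ± 0.325 and 5.32 ± 0.541 RPKM in the cerebellum, above every wild-type value in 4 of 4 knockout mice of each tissue. Of the next genes, none passed: the tRNA guanylyltransferase gene Thg1l (-0.50, SE 0.0869), the calcium channel subunit gene Cacnb3 (-0.33, SE 0.0578) and the RNA-editing family gene Adarb2 (0.54, SE 0.0944) had adjusted p = 0.106, and the interferon-induced gene Xaf1 (-0.71, SE 0.13) adjusted p = 0.118. Leaving out 1 mouse kept both called genes in 3 of 8 fits and 1 of them in the rest. In all, 1925 of 15587 genes had an unadjusted p under 0.05 (736 higher, 1189 lower). Another ribosomal protein pseudogene, Rps15a-ps8 (chromosome 4, 53791070 to 53791456), had 0 or 1 read in each of the 8 wild-type libraries, 6 to 17 reads in the knockout cortex and 8 to 15 in the knockout cerebellum, where limma gave adjusted p = 0.0594; its reads too can be shared with near-identical copies.

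Rps13-ps1 rose in all 8 knockout libraries. Reads moved from other Rps13 copies cannot be told apart from a true gain, since in the cortex the other copies lost 49.6% of the reads that Rps13-ps1 gained, with an SE range of 16.7% to 82.6%, and in the cerebellum 208% of them (590 reads lost, 284 gained), where 78 of 79 cytosolic ribosomal protein genes had negative fold changes. A strain segment around it cannot be told apart either: of the 104 tested genes within 5 Mb, 14.4% had an unadjusted p under 0.05 in both tissues' mean, against 12.3% elsewhere (Fisher's exact two-sided p = 0.548), which leaves a variant in the pseudogene alone open. A sequence variant in an Rps13 copy that moves reads between copies, at a dosage that differs between knockout mice, may contribute: Rps13-ps2 had 18 reads in the cortex of knockout mouse 2, which had the most Rps13-ps1 reads, 559, against 125 to 129 in the other knockout mice and 197 to 234 in wild-type mice, and 10 reads in its cerebellum. An effect of Mecp2 loss itself stays open.

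Long genes were higher than other genes in the knockout cerebellum by 0.148 on the log2 scale. The values are consistent with a length trend that single libraries carry without a difference in genotype, since 1 wild-type cerebellum library against the other 3 gave a Spearman correlation with span of up to 0.317 in size, against 0.281 for the knockout contrast. A trend in exon length and GC content may contribute too, since the difference was 0.0306 once that trend was removed. The removal did not spare differences between genotypes, so a true effect on long genes could have been taken out with it. A genotype effect on long genes thus stays open.

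The 35 splits of the 8 mice into 4 and 4, the real one included, tested whether chance can be excluded. It could not for the counts of genes: in the cortex 6 splits called at least the real 1 gene (highest other split, 6 genes), in the cerebellum 11 (real 1; highest other, 3666), and for the mean of both tissues 6 (real 2; highest other, 12). For the interaction, a real count of 0 is reached by all 35 splits (highest other, 1429), so this count decides nothing. The split that called 3666 genes exchanges wild-type mouse 1 and knockout mouse 1 and keeps the other 6 mice in their groups, which points to a structure of the cerebellum libraries that follows genotype only in part; its cause was not tested. Nor could it for the lists, where 26 splits in the cortex gave at least the real 9 (highest other, 16) and 9 in the cerebellum gave at least the real 20 (highest other, 23). For the length correlation, 18 splits in the cortex were as large (real 0.0279; highest other, 0.121) and 11 in the cerebellum (real 0.281; highest other, 0.380), and for the correlation of the tissues' effects 12 (real 0.238; highest other, 0.400). Of the 35 splits of the 8 wild-type libraries, the real one by tissue called 2809 genes and the highest other 1. Every other split puts both tissues in each group, which widens the spread within groups, and each mouse gave 2 libraries. This gap therefore does not by itself exclude chance. By genes at an unadjusted p under 0.05, 11 splits were as large in the cortex (real 808; highest other, 1800), 3 in the cerebellum (real 2544; highest other, 6234) and 4 for the interaction (real 1571; highest other, 4389).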
